A study of Drosophila melanogaster with 2 samples.

How the data were processed

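Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the protein made by the Drosophila melanogaster gene CG10462 sits on the genome. Per the labels, the flies carried a transgene coding for CG10462 with green fluorescent protein at its C-terminal end, and an antibody to that tag was used for the precipitation. The material was whole embryos 0 to 24 hours old of both sexes pooled, and chromatin was broken by sonication into fragments of 200 to 800 bp. There were 2 samples in 1 group, labelled biological replicates 2 and 3. The labels point to a different protocol document for each replicate. An untagged or input sample was not analysed here.

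The authors deposited peak lists for genome builds dm6 and dm3, and every position below is in dm6, counted from 1. Per the sample notes among the deposited files, a relaxed list holding peaks and background was called for each replicate and for the pooled reads, each against 1 control, and the optimal list was derived from these by the irreproducible discovery rate (IDR), a measure of how well ranks agree between replicates. The aligner, the peak caller and their versions are not given in the sources used here. Each peak has a deposited signal value from the authors' caller, whose scaling is not stated, so it was used mainly to rank peaks within a list. Its size also entered the Pearson correlation between replicates and the plot of that comparison, both on a log scale. It was quoted as well for the peak at the tagged gene. The deposited −log10 q-value was 3.82 for every peak of the optimal dm6 list and was not used to rank. The lists give no read counts, so the depth of each sample is unknown, and intervals below cover the sampling of peaks or genes only. Each relaxed dm6 list held 30000 entries.

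Transcript starts came from Ensembl release 115 (24111 distinct entries of gene, position and strand; transposable elements left out) and sequence from the Release 6 assembly, which is the dm6 build; no dm6 optimal peak ran past a chromosome end or had its summit on an unknown base. A summit within 500 bp of a start was called a promoter summit, and a gene was called occupied if any of its starts had a summit within 500 bp. Promoter share was compared with 10000 random placements that kept the number per chromosome, two-sided. Replicates were compared by the share of the strongest peaks of replicate 2, as many as the optimal list holds, that overlapped by at least 1 bp a peak among as many of replicate 3, against 1000 random placements, one-sided. Correlations across peaks had permutation p-values from 100000 resamples. Density on X was set against 2L, 2R, 3L and 3R by an exact conditional test. For 31 gene lists, Fisher's exact test compared occupied members with all other genes of the same class (13968 protein-coding or 4309 noncoding genes), and 32 consensus sequences were tested by an exact McNemar test between the 100 bp around the summit and the 100 bp centred 400 bp to the left; both families were adjusted by Benjamini-Hochberg at 0.05, two-sided. Sequences of 8 bases were ranked on 2L, 3L and X and the top 10 tested on the remaining chromosomes with Bonferroni adjustment. Shares have 95% Wilson intervals; the share of summits upstream of the start has an exact interval. Peaks and genes are not biological replicates, so these p-values describe the combined list and not the spread between embryos.

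The gene lists, the rule for naming genes, and most tests and alternatives were fixed before the data were examined; the exceptions are given where their values stand. By that rule are named CG10462; the gene at, holding or nearest to each of the 15 strongest peaks; the 4 occupied members with the highest signal of each list past the threshold with a higher share; up to 3 such members of the Hox, gap, pair-rule, segment polarity, dorsoventral, neuroblast and Polycomb and Trithorax lists; and the 5 genes with the most summits from 2 kb upstream to their end, ties kept. Outside the rule, pnut was named after its values were seen, and Dl as a list name without a matching gene. Alternatives were other distances, overlaps and list sizes, protein-coding starts, the stronger part of the list, build dm3, other flanks and windows, and each replicate alone. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated lists of 3000 peaks the placement test called 60 of 1000 uniform lists and returned a promoter share of 40% where 40% had been put in. With 13865 simulated genes and lists of 60 genes, the list test called 9 of 10 lists raised from 15% to 40% and 0 of 20 unchanged ones. Most of the real lists were shorter, so this rate does not carry over to them.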

Results

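The data describe where tagged CG10462, an uncharacterized protein in the reference annotation, was found on the chromatin of whole fly embryos. They comprise 2 biological replicates of 1 group, so the only comparison between samples is of the replicates with each other. The optimal IDR list held 2993 peaks in dm6 and 2786 in dm3. The dm6 peaks had a median width of 416 bp, and they were exactly the 2993 strongest entries of the pooled relaxed list.

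The 2 strongest peaks were the same in both replicates. The top peak, with a summit at 2L position 481076 in an intron of ush (u-shaped, a transcriptional cofactor), ranked 1 in the combined list and in each replicate. The peak 98 bp upstream of a start of CG14100 on 3L ranked 2 in all of them, and the peak 206 bp upstream of a start of px ranked 3 in replicate 2 and 4 in replicate 3. Of the 100 strongest peaks of replicate 2, 89 overlapped a peak within the top 200 of replicate 3, and the one ranked 96 was at 5223 there. In the other direction the number was 94 of 100, and 1 had no entry. Among the 2993 strongest peaks of replicate 2, 2157 (72.1%, interval 70.4 to 73.6%) overlapped one of the 2993 strongest of replicate 3, against a mean of 1.73% for random placement. No placement out of 1000 exceeded 2.51%, which gives the smallest p possible, 0.000999. Over the 2948 optimal peaks with an entry in both replicates, signal correlated with a Spearman rho of 0.61 and a Pearson r of 0.682 on the log10 scale (permutation p = 1e-05 for both, the smallest possible). The list holds the strongest pooled entries, to which both replicates contributed, so these correlations across peaks describe that list only. Of its peaks 43 had no entry in replicate 3 and 2 had none in replicate 2.

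**Figure D1:**
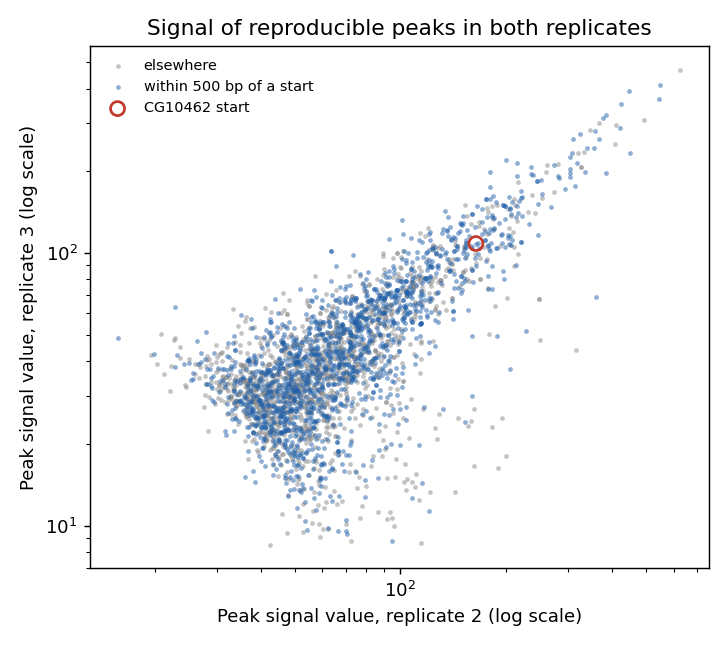
Signal value of each optimal peak in replicate 2 (horizontal, log scale) and replicate 3 (vertical, log scale), with promoter peaks in blue, other peaks in grey and the peak at the CG10462 start ringed. The 2948 points follow a Spearman rho of 0.61.

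The strongest peaks lay at genes of varied known function. Chro, which encodes the chromosomal protein Chromator, had a peak ranked 4 with its summit at 3L position 22878904, 80 bp downstream of a start. Ugalt, a UDP-galactose transporter gene, had the peak ranked 6 at X position 2703878, 26 bp upstream of a start. Peaks at starts of Art3 (an arginine methyltransferase gene), ph-p (polyhomeotic proximal, a Polycomb group gene), PNPase, cass, CHMP2B and mRpL41 (a mitochondrial ribosomal protein gene) ranked 8, 9, 10, 11, 14 and 15, with cass at 5 in replicate 2 and 23 in replicate 3. Introns held the peaks ranked 5 in CG11050 (4 in replicate 2 and 8 in replicate 3), 12 in the overlapping HMG-box genes HmgD and HmgZ, and 13 in the kinase gene Lk6. The peak ranked 7 was intergenic, at 2R position 13035337, and its nearest gene was CG13323, whose start was 11919 bp away. By number, lncRNA:CR44357 had 14 summits, CG1677, which it overlaps, and kirre (a muscle cell adhesion gene) had 13 each, tara had 11, and sbb and ush had 9 each. Of these, tara was the densest at 0.30 summits per kb. The longest, kirre at 394 kb, was the sparsest at 0.033 per kb, and lncRNA:CR44357 at 239 kb had 0.058 per kb.

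CG10462 itself had a peak at its own start. The summit, at 2L position 19735920, was 60 bp inside the gene (2L 19732080 to 19735980, minus strand), and the peak ranked 169 in the combined list, 167 in replicate 2 and 166 in replicate 3. Its signal value was 265 in the combined list. The other 6 pooled entries within 20 kb of the gene had ranks from 10324 to 22981. A transgene can add copies of this locus, and no untagged sample was used here to measure that.

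Peaks were concentrated at transcript starts. Of the 2993 summits, 1603 (53.6%, interval 51.8 to 55.3%) lay within 500 bp of a start, 3.94 times the 13.6% for random placement. No placement out of 10000 reached the observed share, which gives the smallest p possible, 0.0002. Introns held 949 summits (31.7%, against 39.3% for random positions) and intergenic sequence 366 (12.2%, against 27.3%). Coding exons held 7 summits, 0.234% against 13.9% for random positions. The promoter share was 63.0% among the strongest of 4 equal classes of peaks by signal, then 52.9%, 50.4% and 47.9% (Spearman rho of signal with promoter status 0.11 across peaks, permutation p = 1e-05, the smallest possible). Along the pooled relaxed list it fell to 18.8% among the last 3000 entries.

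**Figure D2:**
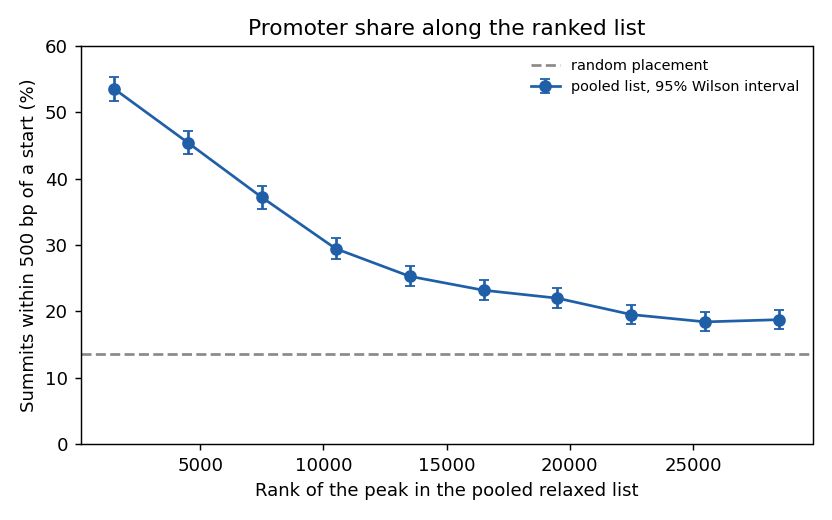
Share of summits within 500 bp of a transcript start (vertical, percent) in successive bins of 3000 entries of the pooled list by rank (horizontal), with 95% Wilson intervals; the dashed line is random placement at 13.6%. The share goes from 53.6% in the first bin to 18.8% in the last.

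Promoter summits sat mostly upstream of the start. Of 1599 that could be given a side, 1367 (85.5%, exact interval 83.7 to 87.2%) were upstream of the nearest start and 232 downstream (exact binomial p = 1.13e-195). The median summit was 119 bp upstream, and 59.8% of the 1603 promoter summits lay in the 200 bp before the start.

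**Figure D3:**
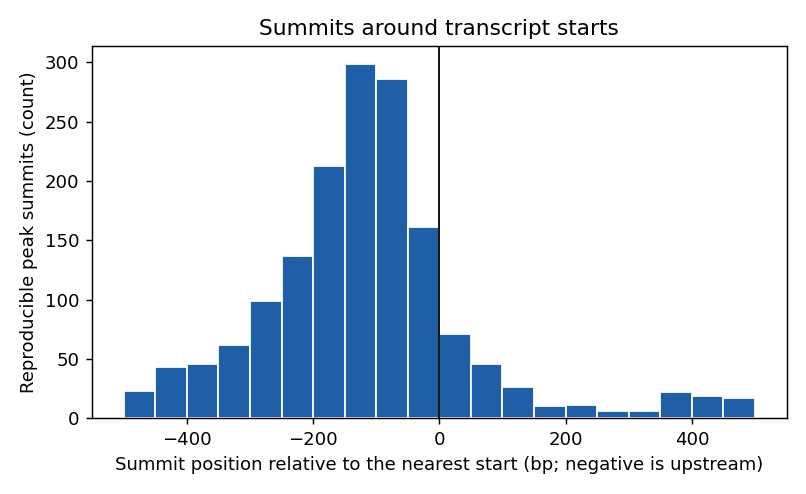
Number of promoter summits (vertical) by position relative to the nearest transcript start (horizontal, bp, negative upstream) in bins of 50 bp. The median lies 119 bp upstream.

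Chromosome 4 had the lowest density among the chromosomes with any peak. Peaks per Mb were 24.9 on 2L (exact interval 22.9 to 27.0), 19.9 on 2R (18.2 to 21.7), 23.7 on 3L (21.9 to 25.6), 22.5 on 3R (20.9 to 24.2) and 21.9 on X. The main autosome arms were not tested against each other. The ratio of X to the 4 main autosome arms was 0.962 (exact interval 0.873 to 1.06, p = 0.443), a comparison that bears on whether the single X of males lowers its peak number; it did not pass the threshold. Counted per coding gene, the ratio was 1.10 (exact interval 1.00 to 1.21, p = 0.0449), so its direction depended on the scale. Chromosome 4 had 8 peaks, or 6.01 per Mb, 0.265 times the main arms (interval 0.114 to 0.522, exact p = 3.43e-06). Per coding gene that ratio was 0.472 (interval 0.204 to 0.932, exact p = 0.0270). The chromosome 4 tests and those per coding gene were added after the counts were seen. The Y chromosome had 0 peaks and also 0 entries in the pooled relaxed list, so the lists do not separate absence from lack of measurement there.

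Ribosomal protein genes stood out among the gene lists. Of 93 such genes, 42 were occupied (45.2%, interval 35.4 to 55.3%), against 14.5% of other protein-coding genes (adjusted p = 2.37e-11, Fisher's exact test). With replicate 3 alone the number was 28 (30.1%, against 13.8%, adjusted exact p = 0.000416) and with replicate 2 alone 49 (52.7%, against 14.4%, 2.53e-16). The highest signals were at RpL11, RpL7, RpS27 and RpL34b, whose peaks ranked 125, 194, 226 and 338. RpL11, RpL7 and RpS27 ranked 74, 140 and 111 in replicate 2, and 258, 397 and 909 in replicate 3. The heat shock list did not pass, with 4 of 17 genes occupied (adjusted Fisher's exact p = 0.647). Nor did other lists of genes used by most cells. Translation factor genes had 11 of 54 occupied (adjusted exact p = 0.619), proteasome genes 5 of 32 (0.923) and respiratory chain genes 14 of 84 (0.904). Splicing genes had 6 of 26 (adjusted exact p = 0.619), cell cycle and replication genes 8 of 35 (0.619) and mitochondrial ribosomal protein genes 19 of 73 (0.0507). Over the alternatives the adjusted exact p of the last ran from 0.0474 with protein-coding starts, where its counts were the same and fewer lists were adjusted for, to 1 with nearest starts, where 8 of 73 were occupied.

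Smaller lists of Notch pathway and insulator protein genes had higher shares that depended on the setting. Notch pathway genes were occupied in 9 of 25 cases (36.0%, adjusted exact p = 0.0374), led by E(spl)m3-HLH, numb, E(spl)mdelta-HLH and E(spl)m7-HLH at ranks 217, 269, 393 and 484. Of the 26 names written for this list, Dl matched no unique gene and was not tested. In replicate 3, E(spl)m3-HLH ranked 354 and E(spl)m7-HLH 999, and in replicate 2 they ranked 176 and 329. The E(spl) genes code for repressors that respond to Notch, and numb for an inhibitor of it. Insulator and architectural protein genes were occupied in 7 of 17 cases (41.2%, adjusted exact p = 0.0374), led by Chro, Cp190, M1BP and Dref at ranks 4, 163, 669 and 976. The Dref peak, which also counted for a gene of the ribosomal protein list, ranked 585 in replicate 2 and 2577 in replicate 3. Another occupied member, pnut, codes for a septin of the cytoskeleton; without it, an alternative chosen after seeing the data, the list had 6 of 16 (37.5%) and an adjusted exact p of 0.0878, which did not pass, and the Notch list was at 0.0421. With replicate 3 alone the adjusted p was 0.102 for the Notch list and 0.261 for the insulator list, and with replicate 2 alone the Notch list was at 0.0798. Giving each summit to its nearest start, an alternative chosen after seeing the data, left them at 0.149 and 0.235; distances of 200 bp (Notch, 0.988) or 1000 bp (insulator, 0.0572) and the stronger part of the list (0.216 for both) also ended the calls. So did leaving out the genes named uncharacterized, likewise chosen after seeing the data, which raised the share among other genes to 18.1% (adjusted exact p = 0.146 for the Notch and 0.118 for the insulator list).

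Chemosensory receptor and cuticle genes were left out of the occupied set. Of 179 odorant, gustatory and ionotropic receptor genes 0 were occupied (interval 0 to 2.10%, adjusted exact p = 2.37e-11), and of 114 cuticle genes 0 (interval 0 to 3.26%, adjusted p = 2.63e-07). In the pooled relaxed list 20 and 14 of these genes had an entry. Replicative histone genes also had 0 of 111 (adjusted exact p = 2.99e-07), but they had 0 in the relaxed list too, where 51.2% of other genes had an entry; these genes lie in a repeated cluster, and the lists do not show whether it could be measured.

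No list of embryonic patterning genes passed the threshold in either direction. The gap and pair-rule lists had 0 of 10 genes each (adjusted exact p = 0.647 for both). That is the lowest count possible, and its unadjusted exact p was 0.376. In the test of product name words given below, 0 of 22 genes had an unadjusted Fisher's exact p of 0.0633 and 0 of 29 had 0.0163. Among the gene lists, an unadjusted exact p of 0.0114 did not pass. Lists of 25 genes or fewer therefore could not pass on the lower side, and whether they are depleted stays undecided. Among Hox genes 1 of 8 was occupied, Dfd (Deformed) at rank 2386 (2206 in replicate 2 and 3462 in replicate 3). Among segment polarity genes 1 of 15 was, nkd (naked cuticle) at rank 513 (394 in replicate 2 and 907 in replicate 3). Of dorsoventral genes htl (a fibroblast growth factor receptor gene) at rank 1182 and ush at rank 2861 were occupied among 25, and of neuroblast genes insc (inscuteable) at rank 1436 among 21. Maternal patterning genes had 3 of 19, neuron genes 1 of 21, glial genes 1 of 12, muscle genes 5 of 30, tracheal and salivary gland genes 2 of 16, and gut, fat and blood cell genes 3 of 21. Polycomb and Trithorax group genes had 9 of 30 (adjusted exact p = 0.101), with ph-p, ph-d and brm at ranks 9, 71 and 341 (ph-d at 57 in replicate 2 and 109 in replicate 3). That list passed at 200 bp (adjusted exact p = 0.0386), with replicate 2 alone (0.0426) and with nearest starts (0.0157), but not with replicate 3 alone (0.228), at 1000 bp (0.207) or with the stronger part of the list (0.289). Germline genes had 7 of 21 and the eggshell, yolk and testis list 1 of 41 (adjusted exact p = 0.0878 for both). The 1 occupied member of the latter was Cp190, the insulator protein gene named above, which entered that list only through its name. None of the other members was occupied, and the list was not tested without Cp190. Without the genes named uncharacterized it passed on the lower side (adjusted exact p = 0.0251). Dosage compensation genes had 0 of 6, tRNA genes 9 of 295, and small nuclear and nucleolar RNA genes 9 of 306. At 1000 bp the last list passed on the higher side, with 34 of 306 (11.1%, against 6.50% of other noncoding genes, adjusted exact p = 0.0226).

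**Figure D4:**
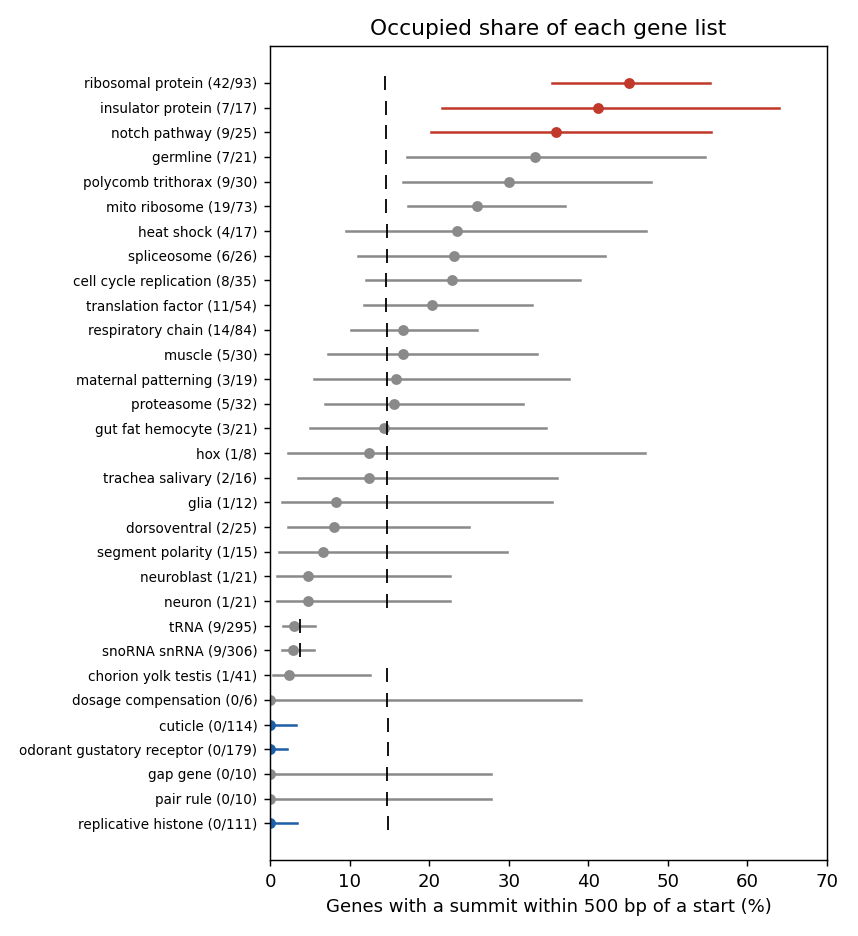
Share of each list's genes with a summit within 500 bp of a start (horizontal, percent; points with 95% Wilson intervals) and the share among other genes of the same class (black ticks). Lists past the adjusted threshold are red where higher and blue where lower; ribosomal protein genes reach 45.2%.

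Summits lay on AT-rich sequence. The central 100 bp held 32.8% G and C bases (SD 8.60 across 2993 peaks), against 44.7% in the left and 44.3% in the right flank, and 2500 peaks (83.5%) were lower in the centre than in their flanks. The centre held 33.1% at promoter peaks, 31.8% at intron peaks and 33.3% at intergenic peaks. Of 32 consensus sequences 20 passed the threshold, 12 with more matches in the centre and 8 with more in the flank. TATCGATA, the DNA replication-related element, was in 44 centres and 9 left flanks (adjusted exact McNemar p = 4.34e-06), and the CTCF consensus in 33 and 7 (7.79e-05). The homeodomain core TAATTA, which is made only of A and T, was in 300 and 147 (5.28e-13) and the GATA consensus in 507 and 334 (1.23e-09). On the flank side, the GGGCGG sequence was in 33 centres and 146 flanks (4.18e-17) and the GAGA sequence in 33 and 101 (2.1e-08). The 10 leading 8-base sequences held only A and T, and 10 of 10 passed on the chromosomes kept apart. Of these, ATTTAAAA was in 91 centres and 11 flanks of 1231 peaks (exact McNemar p with Bonferroni adjustment = 7.97e-16). Some of the 10 were shifted forms of one another. They were not set against composition, so their passing cannot be told apart from the AT-rich centres.

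**Figure D5:**
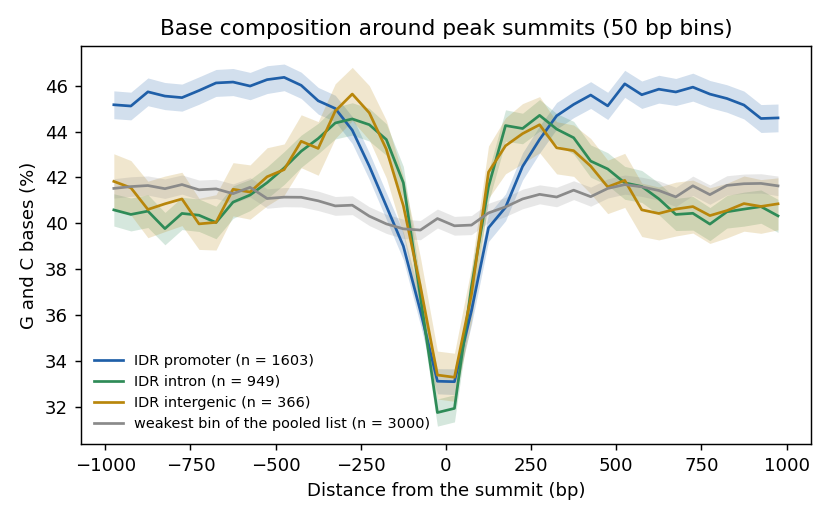
G and C content (vertical, percent, bins of 50 bp, with 95% bands) by distance from the summit (horizontal, bp) for optimal peaks in promoters, introns and intergenic sequence and for the weakest 3000 entries of the pooled list. The 100 bp centre is at 33.1%, 31.8% and 33.3% in the optimal classes.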

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

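The tests on the rank, promoter share and base composition of missing peaks, that on other genes used by most cells, and those on consensus sequences inside the range of their shuffled letters, with 1 match moved or against the right flank were chosen only after the result was seen. The values that follow come from entries outside the optimal dm6 list, on which most of the report rests. The pooled entries ranked 2994 to 5986, just below the optimal list, had a promoter share of 45.5% (interval 43.7 to 47.3%), against 13.6% for random placement. On chromosome 4 the pooled relaxed list held 381 entries per Mb, while that chromosome had the lowest density of optimal peaks among those with any. In dm3, replicate 3 had 367 entries on heterochromatin or unplaced sequence and replicate 2 had 66.

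Among the strongest peaks of replicate 2, 181 had no entry in the whole list of replicate 3, and 41 strong peaks of replicate 3 had none in replicate 2. Entries split in one list and merged in the other are argued against as the source of most missing replicate 2 peaks. Of these peaks, 1.10% (interval 0.304 to 3.94%) lay within 500 bp of a stronger peak of their list. The share was 4.37% among the overlapped peaks, but that difference decides nothing. A split peak that overlapped a merged entry did not count as missing, which can lower the share among missing peaks. The missing peaks had a median rank of 2236 (interval 2007 to 2394) among 2993, as lower sensitivity of replicate 3 would give, but weakness was not their only difference from overlapped peaks of the same ranks: 40.9% were promoter peaks against 53.6% (the share fell by 12.7 percentage points, interval -20.2 to -5.21), and their centres held 38.4% G and C against 33.6% (difference 4.77 percentage points, interval 3.51 to 6.02). Lower sensitivity and background particular to replicate 2 both stay open, since the ranks go with the former but leave the other differences unexplained. Open too is any difference between the separate protocol documents that the labels point to, whose content was not used here, and no biological explanation was tested.

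The AT-rich centre was deeper than at promoters without a summit. Windows at the same offsets from 1603 starts without a summit within 1000 bp held 40.2% G and C, so occupied centres fell by 7.09 percentage points (interval -7.78 to -6.39). Composition shared with such promoters therefore does not account for the whole dip. It may account for part, since the flanks of occupied promoter peaks held 45.7% and 45.4%. The control starts were not chosen for activity in embryos, so a composition shared by active promoters stays open. A bias of sequencing or calling toward AT-rich DNA stays open: of promoter windows with at most 32.0% G and C, 16.8% had a summit within 500 bp, against 8.43% of the others; the bound set beforehand, a majority, was too strict, because a partial bias would raise this share without reaching it. TAATTA, GGGCGG and the A run had too few other orders of their letters to be set against composition. Of the other 17 called consensus sequences, 5 lay outside the range of their own letters in other orders. The M1BP, Motif 7 and CTCF sequences stayed above that range with 1 match more in the flank and against the right flank. Only sequences already called for an unequal ratio in these peaks were tested, which favours a place outside the range. Composition alone is argued against for CTCF, whose centre-to-flank ratio (1 added to each count) was 4.25 against an upper limit of 1.00. For M1BP (2.83 against 2.00) and Motif 7 (1.56 against 1.45) it stays open, as both were near the upper end of their range. Motif 6, with 0 flank matches, and the CA repeat came inside it with 1 match moved and decide nothing; by adjusted exact p, the call of Motif 6 was lost against the right flank (1), with replicate 3 alone (0.402) and with the stronger part of the list (0.235), and those of M1BP and Motif 7 with the latter (0.486 and 0.402). The other 12 lay inside that range, the GATA sequence and TATCGATA among them (the latter above it against the right flank), and cannot be told apart from composition, since they were picked for lying there.

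The higher share of ribosomal protein genes did not come from neighbouring starts: with each summit given to its nearest start, 37 of 93 (39.8%) were occupied against 10.1% of other genes, with an adjusted p of 2.57e-12. Nor was it the level of the other lists of genes used by most cells. The translation factor, proteasome, respiratory chain and splicing lists, a pool chosen after the result was seen, had 36 of 196 (18.4%, interval 13.6 to 24.4%, exact p = 3.94e-06 for the difference). A wider pool had 67 of 321 (20.9%, interval 16.8 to 25.6%, exact p = 7.49e-06). It added the cell cycle and mitochondrial ribosomal lists, and also the heat shock list, which is not one of genes used by most cells. Signal that rises with transcription in any ChIP stays open, because neither expression nor an untagged sample was used here; no biological explanation was tested.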

How the results depend on the processing

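The nearest-start, distinct-summit and own-locus alternatives, the ranks of named genes in single replicates, the X ratio per coding gene, the insulator list without pnut and the background without uncharacterized genes were chosen after seeing the data. The ratio of X to autosome density, 0.962, turned to 1.01 with replicate 3 alone (exact p = 0.848) and was 0.913 with replicate 2 alone; per coding gene it was 1.10 and passed (exact p = 0.0449), as X holds fewer coding genes per Mb. With the stronger part of the list, 13 consensus sequences passed in place of 20, all of them among the 20; fewer peaks entered that test. The rank of the CG10462 peak, 169, was 166 to 167 in the single replicates. The share of small nuclear and nucleolar RNA genes, 2.94% and below that of other noncoding genes, turned above theirs at 1000 bp (11.1%) and with replicate 2 alone (3.92%), and was 3.27% with replicate 3 alone; the cause was not tested. The other 49 values of the main results kept their direction and side of the threshold, or stayed within 1.5 times for counts: replicate overlap ran from 64.4 to 73.9%, the promoter share from 37.2% at 200 bp to 63.3% at 1000 bp, upstream summits from 83.0 to 86.5%, and lists past the threshold from 4 to 7. Taking the strongest pooled entries moved nothing, since they are the optimal list. The dm3 alternative for the X ratio was not run, as no dm3 genome was used here. Depth is unknown, so no limit from read number can be given.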

Other observations

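Words in the reference product names of genes were tested after the main results were seen, 115 words with at least 20 genes each over 13968 protein-coding genes, by Fisher's exact test with Benjamini-Hochberg adjustment. Of these 19 were more frequent and 8 less frequent among occupied genes. Genes named uncharacterized, the class CG10462 itself is in, had 622 of 6115 occupied (10.2%, against 18.1% of the others, adjusted exact p = 6.31e-39), which lowers the share that other words are set against. Over the 7853 genes not named so, 10 words passed, each of which also passed over all genes, with 3 more frequent and 7 less frequent. The 3 were ribosomal with 61 of 170 genes (35.9%, against 17.8% of other genes, adjusted exact p = 1.04e-06), domain with 40 of 137 (29.2%, 0.0198) and biosynthesis with 11 of 26 (42.3%, 0.0411). Of the less frequent, receptor had 14 of 341 genes (4.11%, 4.05e-13), odorant 1 of 111 (0.901%, 4.03e-07), and glycosyltransferase 0 of 35 (adjusted exact p = 0.0198). Genes named ribosomal, receptor or odorant include members of the lists tested above on the same peaks, so these words are not separate support.

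A hypothesis written before any test was that occupied promoters tend to lie in divergent pairs, in which starts on opposite strands point away from each other within 1000 bp. Of 3020 divergent promoter regions 745 had a summit (24.7%, interval 23.2 to 26.2%), against 738 of 12044 regions with starts on 1 strand (6.13%, Fisher's exact p = 2.08e-168). The comparison by region was chosen after a count per base had been seen, since divergent regions hold more starts. If each region had only offered 2 independent starts, 11.9% would have had one. Divergent regions had 2.82 annotated starts on average and the others 1.22. The excess may come from regions on 1 strand holding more genes silent in embryos, which was not tested.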
